A study of Mus musculus with 47 samples.

How the data were processed

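ChIP-seq peak lists were taken for 4 antibodies, against Myc, RNA polymerase II (RNAPII), H3K4me3 and H3K27ac, in control liver, in liver tumours with the tet-Myc transgene on and in liver tumours with it off for 16 h. The series held 47 samples, of which 46 had a peak list and were used. The input sample was not analysed here. Each library had its own list, so peaks were called per library and not on pooled samples. Groups and replicate numbers came from the submitters' titles, tissue and genotype labels. Of the control livers, number 1 carried tet-Myc without expression, number 2 carried LAPtTA, and numbers 3 and 4 were wild type, per the labels. The treatment protocol named a wild-type and a mutant tet-Myc, and the labels did not say which form each tumour expressed. The labels did not state that libraries of a group came from separate animals. The genotypes show only that control liver 1, control liver 2 and the wild-type ones came from different animals. So p-values measure the spread between these samples, which may be technical where animals are not known to differ.

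Per the submitters' processing notes, the tools included BWA 0.6.2 and SAMtools, and the genome build was mm9. The Myc lists carried peak names of the MACS type, and their last column held the authors' score for each peak, whose scale was not given in the sources used here. The H3K4me3 and H3K27ac lists were in a gapped-peak layout with MACS peak names and a track line pointing to a broad call, and they held a whole-number score, as deposited by the authors. The RNAPII lists held positions only, and the caller was not given in the sources used here. The caller's version, threshold and control library were not given in the sources used here for any antibody. Scores were used only to rank or filter peaks. The stricter score limit was the median score of all peaks of an antibody, the same for all its libraries. It therefore removed more peaks from libraries with lower scores. The lists gave no read counts, so the depth of each library is unknown, no counting interval could be given, and a region without a peak means only that no peak was called there. No further tool was applied to reads.

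The design fixed before the data were examined used promoter windows where an annotation of the same build was at hand, and merged regions otherwise. The gene table used here was of GRCm38.p6, another build than mm9, so the region version of every test was run, no coordinate was converted and no gene is named. For each antibody, peaks of all its libraries were merged wherever they overlapped by at least 1 bp. Regions covered in at least 2 libraries were kept, and the value per library was the percent of the region's length covered by its peaks. Coordinates are given in mm9 and counted from 1. These percents were fitted with limma 3.58.1 in R 4.3.3 (linear model, contrasts, moderated test with a mean-dependent prior variance), with the 3 groups of an antibody in the same fit and no covariate. Regions were called at a Benjamini-Hochberg adjusted p below 0.05, and errors of differences are limma standard errors. Merging was done with numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15, other tests with scipy 1.17.1, and plots with matplotlib 3.10.9. The limma step was tested on simulated data with 200 changed regions per contrast. With 60 percentage points added, it recovered between 39.5% (RNAPII, switched-off tumours against control liver) and 88% (Myc, tumours against control liver) of them. With 30 points it recovered at most 12%, so with few changed regions small shifts in coverage were mostly missed. The adjusted threshold is less strict where many regions change, so these rates do not carry over to contrasts with many called regions.

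Values with a single number per library (peak number, covered length, share of peaks in a class) were compared by two-sided exact permutation of the library labels. The smallest p this allows is 0.00476 for 6 against 4 libraries, 0.0119 for 6 against 3, and 0.0286 for 4 against 4 or 4 against 3. Benjamini-Hochberg adjusted values are given beside most of these p-values under 0.05 and some others. For peak number and other list sizes they are over all contrasts of the same measure. For overlaps with marks, class shares and coverage of Myc-bound regions they are over all contrasts, marks, classes and settings of that kind of test. Regions were classed by overlap with H3K4me3 or H3K27ac regions present in at least 2 libraries of the named group. Myc-bound meant overlap of at least 1 bp with a Myc region present in at least 2 tumours with Myc on. As a background for overlaps, Myc regions were placed at random on their own chromosomes 100 times. Odds ratios across regions were also computed within 5 strata of length by 5 of control coverage. Regions are not independent replicates, so odds ratios describe these libraries. For overlaps of changes between contrasts that share the tumour libraries, 20 simulated data sets without any effect, the overlap of independent lists and a version with the tumour libraries divided between the contrasts were computed.

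Regions named in the text were taken by a rule of the same design. For each antibody, and for tumours against control liver and switched-off tumours against tumours, these were up to 5 regions per direction with the largest difference in mean covered percent. They had to pass the adjusted threshold, be covered in every library of the higher group and be covered in no library of the lower group. The text names some of these, from the top.

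Alternatives were a fit of the compared groups alone, a Fisher exact test on presence, the replicate number as a block, lists shortened to equal lengths, a stricter score limit, no filter on the number of libraries, covered length in place of peak number, other overlap limits, and leaving out each library in turn. Lists were shortened by the authors' score, except the RNAPII lists, which held none and were shortened to their widest peaks. Added after the data were seen were the library mean coverage as a covariate, chromosomes 1 to 19 alone, a term for libraries with Y chromosome peaks, the wild-type control livers alone, and Myc regions built without the longest list. No pair of lists shared more than 2 identical peaks, so no library was counted as a repeat of another.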

Results

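Binding of Myc and RNAPII and the histone marks H3K4me3, which lies mainly at promoters, and H3K27ac, which lies at active promoters and enhancers, were mapped by ChIP-seq in livers of FVB mice. The tumours carried tet-Myc, a Myc transgene driven in liver by the transactivator LAPtTA and silenced by doxycycline. For Myc there were 4 control livers, 6 tumours with Myc on and 3 tumours with Myc off for 16 h. Each of the other antibodies had 4 control livers, 4 tumours with Myc on and 3 tumours with Myc off. The measurement was the list of peaks of each library, and the reads behind each list are unknown. Regions below are merged peaks in mm9, and coverage is the percent of a region's length under the peaks of a library.

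The series title concerns gene activation and repression that depend on Myc in these tumours, and the comparison of tumours with control liver gives the changes present while Myc is on. Myc binding was far wider in tumours than in control liver. Tumour lists held 33786 ± 14095 peaks (SD, n = 6) and control lists 3568 ± 3370 (SD, n = 4), covering 28.1 ± 18.7 Mb and 1.32 ± 2.11 Mb. Control liver 4 carried the control means, with 8499 peaks and 4.47 Mb against at most 2816 peaks and 0.460 Mb in the other 3. All 6 tumour lists were longer than all 4 control lists (exact permutation p = 0.00952, adjusted p = 0.0857), and after adjustment over the 12 contrasts no difference in peak number passed 0.05. In tumours, 38418 Myc regions were present in at least 2 libraries and 13652 in all 6, against 2245 regions in at least 2 control livers. Of the 2245 control regions, 1748 were also present in at least 2 tumours.

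Of 39145 Myc regions tested by limma, 18481 were covered more and 114 less in tumours than in control liver. Peak widths bear on this count. The narrowest peak had 53 to 71 bp in control livers 1 to 3, but 239 to 328 bp in tumours and 293 bp in control liver 4. A control peak can thus cover little of a region. Of 13650 regions present in all 6 tumours, 5923 had a peak in at least 1 control liver. The region on chromosome 18, 66450678 to 66451771, was covered to 89.7% ± 7.60 (SD, n = 6) in tumours and carried no peak in 4 control livers (difference 89.7 ± 10.0 points, limma adjusted p = 1.6e-14). The region on chromosome 11, 72223961 to 72225655, was covered to 87.3% ± 10.5 in tumours and in no control liver. A pair of regions on chromosome 2, starting at 30571735 and 30512948, reached 86.7% ± 8.22 and 85.5% ± 14.4. All 5 named gained regions lay in chromatin that already carried H3K4me3 in control liver, at 100% ± 0 for the chromosome 18 region and 95.4% ± 3.82 for the chromosome 11 region (SD, n = 4). The chromosome 11 region had no H3K27ac peak in control liver and was covered to 99.0% ± 2.01 by H3K27ac in 4 tumours. Among regions bound in control liver alone, chromosome 10, 98847383 to 98847801, was covered to 84.8% ± 13.5 in 4 controls and in no tumour. The region on chromosome 12, 81282596 to 81283159, was covered to 79.9% ± 13.4 in controls, where H3K27ac covered all of it, and neither Myc nor H3K27ac had a peak there in tumours. With all lists shortened to 1002 peaks, the length of the shortest list, by highest score, 792 regions were called and 72% of them were higher. Such a cut removes the difference in peak number in advance. The count also moved by over 1.5 times with a Fisher exact test on presence (7801), a stricter score limit (10172), mean coverage as a covariate (9584) and wild-type controls alone (9863).

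**Figure D1:**
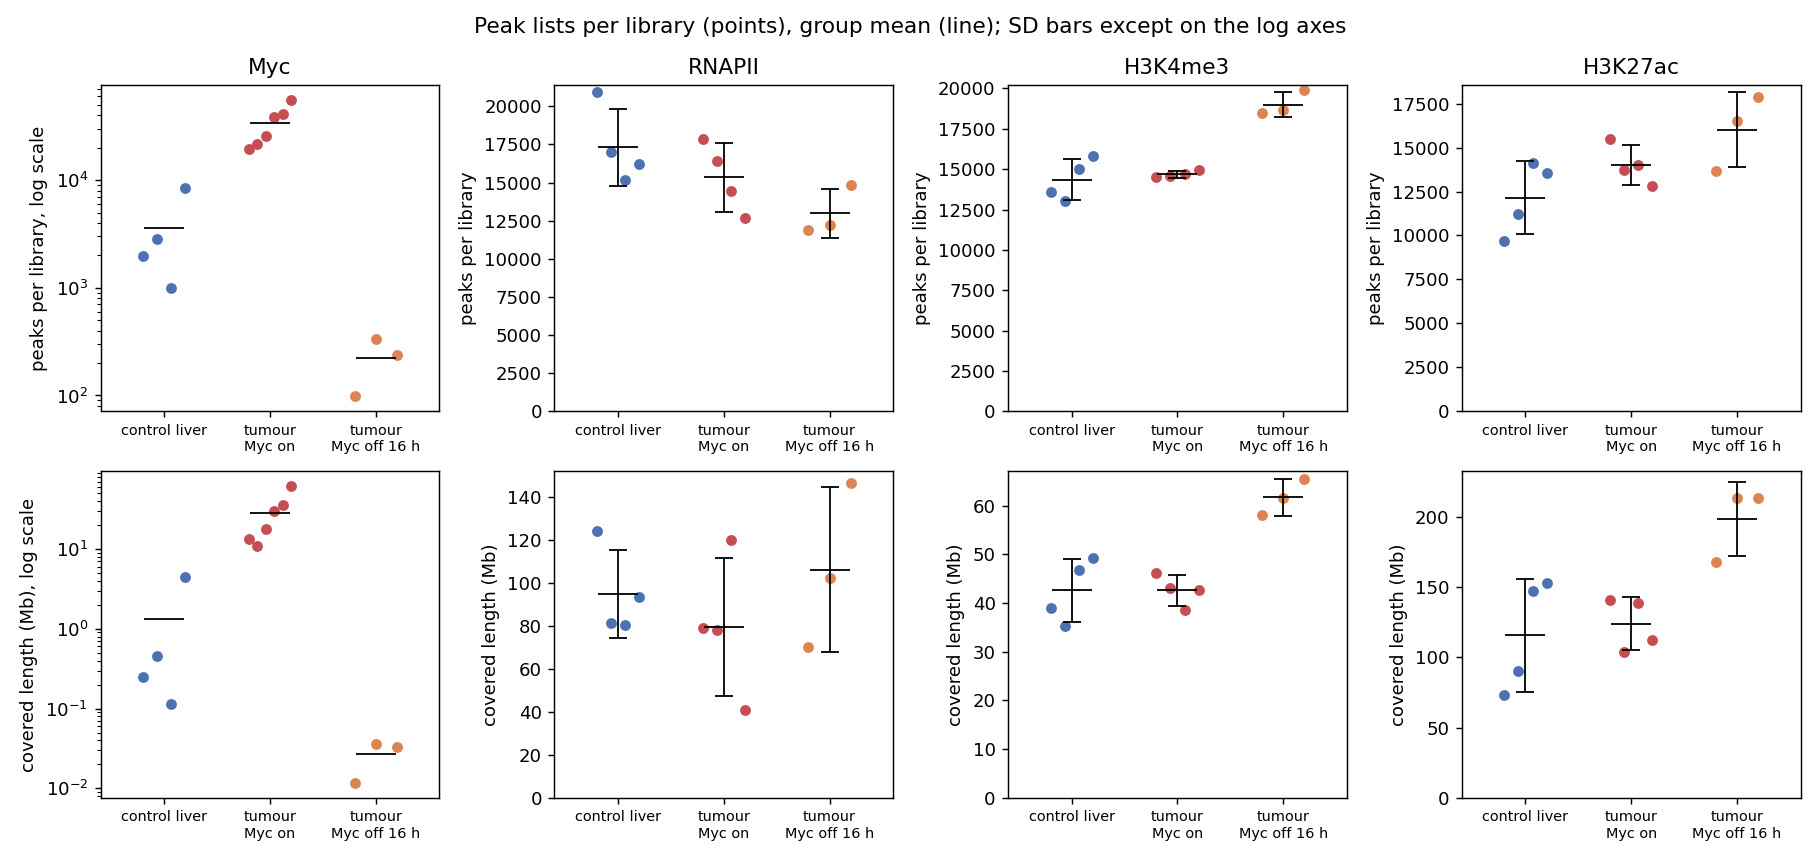
Peaks per library (top) and covered length in Mb (bottom) for Myc, RNAPII, H3K4me3 and H3K27ac; points are libraries, lines are group means and bars SD, with log axes and no bars for Myc. Myc lists hold 19269 to 55763 peaks in tumours, 1002 to 8499 in control liver and 98 to 331 after shutdown.

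Much of the Myc-bound genome lay in chromatin already marked in control liver. Of the 38418 Myc regions, 41.0% overlapped control H3K4me3 regions, 58.7% overlapped control H3K27ac regions and 51.9% overlapped control RNAPII regions. Randomly placed regions overlapped these to 3.22%, 7.82% and 6.62% on average. Of the 13652 regions bound in all 6 tumours, 66.4% overlapped control H3K4me3 regions, 17.6% overlapped control H3K27ac without H3K4me3 and 16.0% overlapped neither. H3K27ac peaks of single libraries overlapped 62.8% ± 4.34 of the Myc regions in tumours and 48.8% ± 10.4 in control liver (SD, n = 4 and 4, exact permutation p = 0.0286, adjusted p = 0.0735). For regions bound in all 6 tumours the H3K27ac shares were 89.3% ± 3.03 and 68.4% ± 11.2 (exact permutation p = 0.0286, adjusted p = 0.0735). The differences rested in part on control livers 1 and 2: the overlap with all Myc regions was 37.1% and 42.8% there, 57.9% and 57.3% in wild-type control livers 3 and 4, and 59.1% in the lowest tumour. H3K4me3 overlapped 38.7% ± 0.678 in tumours and 38.0% ± 2.85 in control liver (exact permutation p = 0.743), and RNAPII 41.9% ± 4.72 and 46.4% ± 4.49 (exact permutation p = 0.314).

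Within each tumour, the peaks with the highest authors' scores lay more often at H3K4me3. In the highest-scoring of 4 equal parts of each list, 72.5% ± 9.20 of peaks overlapped control H3K4me3 regions, and in the lowest-scoring part 36.2% ± 14.1 (SD, n = 6, 6 of 6 tumours, exact sign-flip p = 0.0312). Peaks in neither H3K4me3 nor H3K27ac regions of control liver rose from 13.0% ± 4.77 in the highest-scoring part to 37.4% ± 11.9 in the lowest, in 6 of 6 tumours.

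**Figure D2:**
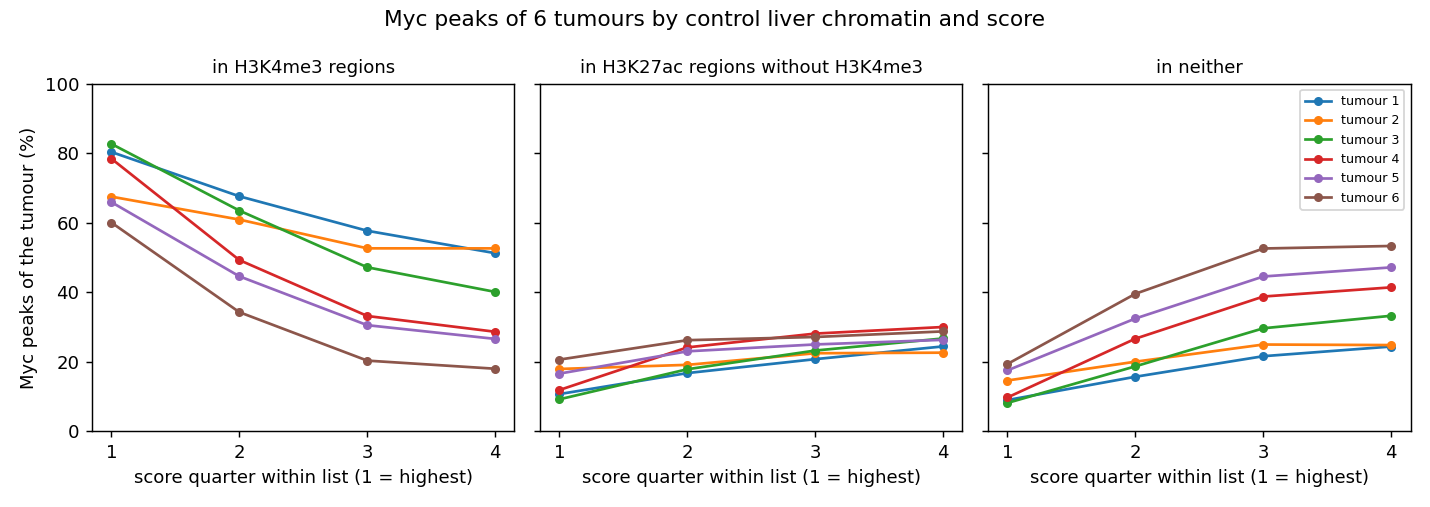
Percent of each tumour's Myc peaks that overlap H3K4me3 regions of control liver (left), H3K27ac regions without H3K4me3 (middle) or neither (right), for 4 equal parts of the list ranked by the authors' score; lines are the 6 tumours. The H3K4me3 share is 72.5% on average in the highest-scoring part and 36.2% in the lowest.

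In tumours more regions were called for loss than for gain of RNAPII, by a margin that varied between settings. Of 16931 regions, 658 were covered more and 1540 less than in control liver (limma). The region on chromosome 4, 107106670 to 107112619, gained RNAPII from no peak in 4 controls to 91.3% ± 7.89 in 4 tumours (difference 91.3 ± 14.4 points, limma adjusted p = 0.000276). There, H3K4me3 covered 90.5% ± 19 in tumours and 22.4% ± 27.6 in controls, H3K27ac covered 97.1% ± 4.83 in tumours and had no control peak, and Myc was bound in 6 of 6 tumours. On chromosome 9, 7787627 to 7799151, RNAPII rose from no peak to 92.4% ± 12.1 without H3K4me3 or H3K27ac peaks in any library. The region on chromosome 7, 27620110 to 27629708, fell from 98.5% ± 1.76 in controls to no peak in tumours (limma adjusted p = 0.000193). On chromosome 13, 64196402 to 64212600, RNAPII fell from 97.8% ± 1.24 to no peak, and H3K27ac covered 60.6% ± 10.7 in controls and had no tumour peak. A domain on chromosome 1, 135146510 to 135202634, fell from 96.8% ± 2.09 to no RNAPII peak. RNAPII peak numbers did not separate the groups, at 15358 ± 2256 in tumours and 17326 ± 2523 in control liver (SD, n = 4 and 4, exact permutation p = 0.343). The number of called regions was 1308 with wild-type controls alone, 1293 without control liver 1, 1347 without tumour 1, 1378 without tumour 2 and 1458 without tumour 3, with more lower than higher regions each time. The share that was higher was 29.9%, but 45.1% of 2762 with mean coverage as a covariate and 44.6% of 2092 without tumour 4. Fisher exact tests on presence called no RNAPII region (1346 at an unadjusted p below 0.05, too few for the smallest possible p of 0.0286 to pass adjustment).

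H3K4me3 changed in both directions, with 1585 regions covered more and 1302 less in tumours among 19506 tested (limma). A pair of the named gained regions lay on chromosome 13, where 22085765 to 22090038 rose from no peak in controls to 91.9% ± 5.02 in 4 tumours, and 23376413 to 23379277 rose to 90.8% ± 5.90 (limma adjusted p = 1.27e-05 for each). On chromosome 9, 62989604 to 62998038 rose to 95.1% ± 5.12. These 3 regions had no RNAPII or H3K27ac peak in any group. At some of the named lost regions the other marks went as well. On chromosome 8, 25682966 to 25687172, H3K4me3 fell from 97.4% ± 2.27, RNAPII from 98.4% ± 1.82 and H3K27ac from 100% ± 0 in 4 controls to no peak in any tumour. On chromosome 15, 96200463 to 96203868, H3K4me3 fell from 97.0% ± 1.81 and H3K27ac from 100% ± 0 to no peak in tumours. On chromosome 4, 19645263 to 19648463, H3K4me3 fell from 95.8% ± 2.45 and RNAPII from 75.8% ± 9.27 to no peak while H3K27ac stayed at 96.9% ± 3.65 and Myc was bound in 6 of 6 tumours. Lists were of like size, with 14675 ± 198 peaks in tumours and 14353 ± 1293 in control liver (exact permutation p = 0.657). The balance of directions depended on the controls: the share of called regions that were higher was 54.9%, 33.2% of 2523 with wild-type controls alone, 44.0% of 2444 without control liver 2, and 48.9% of 3310 with mean coverage as a covariate. A stricter score limit left 321 regions, 95.3% of them higher. Median scores were 8095 and 5985 in control livers 1 and 2, 15097 and 14731 in 3 and 4, and 11255 to 14594 in tumours. The limit of 12027.5 thus removed most peaks of control livers 1 and 2, so this direction is partly built in. Fisher tests called 0 regions (965 at an unadjusted p below 0.05).

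H3K27ac was covered more at 1585 and less at 1056 of 16039 regions in tumours (limma). On chromosome 11, 85061299 to 85075485 rose from no peak in controls to 96.6% ± 1.69 in 4 tumours (difference 96.6 ± 7.69 points, limma adjusted p = 4.08e-05), and 53647838 to 53667905 rose to 94.9% ± 1.49. On chromosome 9, a domain of 53173 bp from 114423776 to 114476948 rose to 93.7% ± 4.83, with RNAPII at 48.3% ± 26.5 in tumours and at no control liver. On chromosome 15, 75252855 to 75265342 fell from 96.4% ± 2.72 in controls to no peak in tumours (limma adjusted p = 0.000104), and RNAPII fell there from 79.2% ± 6.36 to no peak. On chromosome 13, 4043057 to 4064521 fell from 94.4% ± 2.93 to no H3K27ac peak. Peak numbers were 14014 ± 1123 in tumours and 12153 ± 2074 in control liver (SD, n = 4 and 4, exact permutation p = 0.2). The share of called regions that were higher was 60%, but 28.3% of 2974 with wild-type controls alone, 48.3% of 2375 without control liver 1, 49.4% of 1758 with lists of equal length and 49.9% of 3690 with mean coverage as a covariate. A stricter score limit left 310 regions, 90% of them higher. Median scores were 1955 and 2091 in control livers 1 and 2, 3390 and 2756 in 3 and 4, and 2794 to 3329 in tumours. The limit of 2897 thus removed most peaks of control livers 1 and 2, so this direction is partly built in as well. Fisher tests called 0 regions (1324 at an unadjusted p below 0.05).

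Where RNAPII changed in tumours, the histone marks changed in the same direction more often than elsewhere, at fewer than 0.5 of the regions. Of the regions that lost RNAPII and overlapped an H3K4me3 region, 48.7% overlapped a region that lost H3K4me3, against 5.47% of the other RNAPII regions (odds ratio 16.4). Of those that gained RNAPII and overlapped an H3K27ac region, 49.5% overlapped a region that gained H3K27ac, against 10.5% (odds ratio 8.30). Opposite changes were rare, with 3 regions gaining RNAPII and losing H3K4me3 and 2 gaining RNAPII and losing H3K27ac. Regions that lost RNAPII overlapped a gain of H3K4me3 at 18 and of H3K27ac at 19 regions (1.65% and 1.39% of those overlapping the mark). The odds ratios are across regions, which are not independent replicates.

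The gap in coverage between Myc-bound and unbound regions was larger in every tumour than in any control liver for RNAPII, although the difference did not pass after adjustment. Mean RNAPII coverage of Myc-bound regions exceeded that of unbound regions by 18.4 ± 2.46 points in tumours and 8.32 ± 5.24 in control liver (SD, n = 4 and 4, exact permutation p = 0.0286, adjusted p = 0.0643). RNAPII coverage of the bound regions themselves was 35.3% ± 10.9 and 37.5% ± 7.32 (exact permutation p = 0.886), and that of unbound regions 16.9% ± 10.1 and 29.2% ± 12 (exact permutation p = 0.229). For H3K4me3 the excess was 22 ± 5.37 and 20.1 ± 6.10 points (exact permutation p = 0.571). Of the regions with H3K27ac in tumours, 98.9% were Myc-bound. The unbound regions were therefore mostly those without the mark in tumours (3.74% ± 1.73 covered), so the H3K27ac gap follows from this overlap and adds little to it. The share among regions that gained the mark (99.6%) likewise tells little. For binding in all 6 tumours, 81.3% of the regions that gained H3K27ac were bound, against 72.3% of the regions with H3K27ac in tumours. For RNAPII, 82.1% of the gained regions were Myc-bound, against 86.9% of the regions with RNAPII in tumours, while for binding in all 6 tumours the shares were 66.9% and 63.3%. The gained regions were merged over the libraries of all groups, the regions with a mark in tumours over the tumour libraries alone. Longer merged regions overlap Myc more easily, so differences between these shares decide nothing. Binding was taken from tumours alone, so a region bound in control liver alone counts as unbound here, and this selection bears on the RNAPII gap too. With RNAPII lists cut to equal length by keeping the widest peaks, the RNAPII difference was 7.64 points (exact permutation p = 0.0857). It was then not under 0.05 even before adjustment. A cut by width acts on coverage itself.

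**Figure D3:**
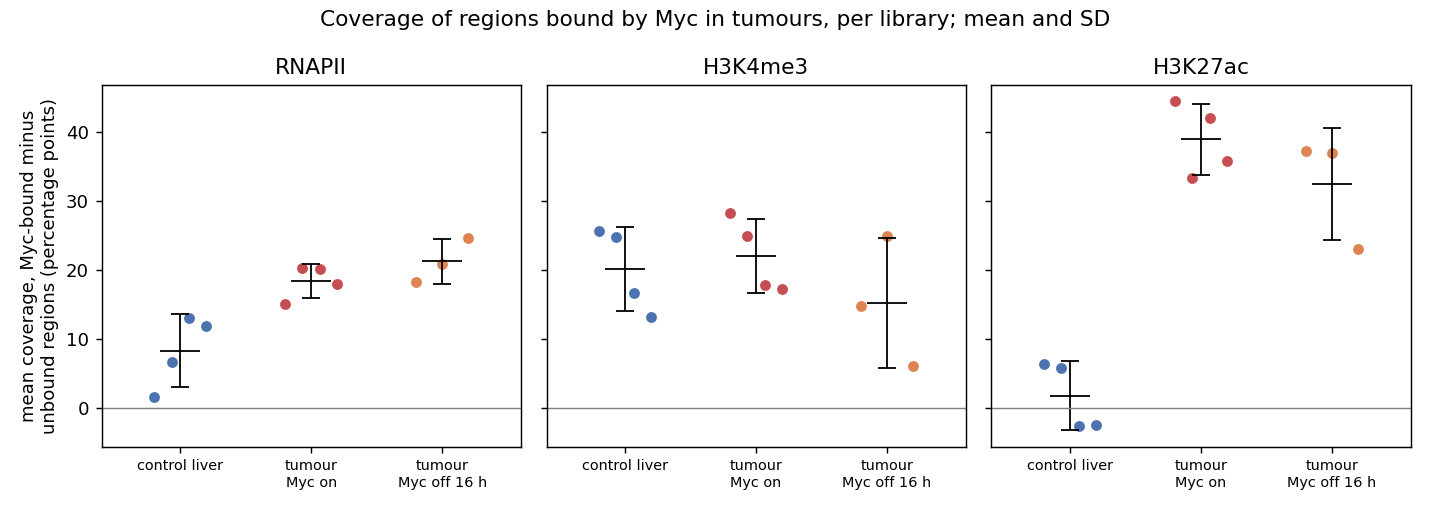
Mean coverage of Myc-bound regions minus that of unbound regions, in percentage points, for RNAPII, H3K4me3 and H3K27ac; points are libraries, lines group means and bars SD. RNAPII stands at 18.4 points in tumours and 8.32 in control liver. The H3K27ac gap follows from the overlap of the mark with Myc, since 98.9% of tumour H3K27ac regions are Myc-bound.

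Shutting off tet-Myc for 16 h left few Myc peaks. Switched-off tumours had 223 ± 117 peaks (SD, n = 3) against 33786 ± 14095 in tumours with Myc on (n = 6, exact permutation p = 0.0238, adjusted p = 0.0857), and they covered 0.0270 ± 0.0133 Mb. Of 39145 regions, 17211 were covered less and 18 more after shutdown (limma). The narrowest peak of the switched-off lists had 51 to 53 bp, so a remaining peak could also cover little of a region. On chromosome 5, 3341061 to 3344995 fell from 90.3% ± 12 in 6 tumours to no peak in 3 switched-off tumours (difference -90.3 ± 10.6 points, limma adjusted p = 6.48e-13), while H3K4me3 and H3K27ac covered all of it in every group. The chromosome 18 and chromosome 11 regions gained in tumours also had no Myc peak after shutdown. On chromosome 4, 15192335 to 15194053 fell from 86.3% ± 12.1 to no Myc peak while RNAPII covered 95.1% ± 4.18 before and 95.0% ± 8.73 after. Of 13650 regions bound in all 6 tumours, merged here over the libraries of all groups, 257 had a peak in any switched-off tumour. Named regions covered more after shutdown included 166 bp on chromosome 6 from 103599063, covered to 93.0% ± 5.47, and 120 bp on chromosome 9 from 3018338, covered to 91.4% ± 2.10. The latter was among 11 regions between 2999852 and 3038237 present in all 3 switched-off tumours and in no tumour with Myc on. Of these 11, 9 also had a peak in a control liver. With all lists shortened to the 98 highest-scoring peaks, 92 regions were called and 62.0% of them were higher after shutdown. This cut removes the difference in peak number in advance and left 294 regions to test, so its direction does not bear on the loss. The count was 8825 with a stricter score limit and 9465 with mean coverage as a covariate.

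RNAPII changed at fewer regions after shutdown, with 411 covered more and 185 less than in tumours with Myc on (limma). On chromosome 7, 3122347 to 3136057 rose from no peak in 4 tumours to 99.1% ± 1.31 in 3 switched-off tumours (difference 99.1 ± 13.7 points, limma adjusted p = 0.000632), with 56.7% ± 8.16 in control liver. On chromosome 11, 5906168 to 5910926 rose to 96.6% ± 3.18, and H3K27ac rose there from no peak to 95.6% ± 1.19. On chromosome 17, 8137625 to 8139128 fell from 90.5% ± 8.31 to no peak, together with H3K4me3 from 100% ± 0 and H3K27ac from 99.5% ± 0.573. On chromosome 13, 22141700 to 22143463, a region with Myc over 76.9% ± 17.9 in tumours and no RNAPII in control liver, RNAPII fell from 88.6% ± 3.26 to no peak while H3K4me3 stayed at 100% ± 0. RNAPII peak numbers were 12996 ± 1600 after shutdown and 15358 ± 2256 before (exact permutation p = 0.171), while covered length went the other way, 106 ± 38.4 Mb against 79.4 ± 32.2 Mb (exact permutation p = 0.371). The count was 154 with the compared groups alone, 1109 with mean coverage as a covariate and 0 by Fisher tests (414 at an unadjusted p below 0.05). Single libraries also set it: 176 without switched-off tumour 2, 344 without 3, 982 without 1, 333 without tumour 1, 363 without tumour 2, and 658 without tumour 4, where 44.8% were higher.

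H3K4me3 lists were longer after shutdown. They held 19006 ± 757 peaks over 61.7 ± 3.77 Mb (SD, n = 3), against 14675 ± 198 peaks over 42.6 ± 3.19 Mb in tumours with Myc on (n = 4, exact permutation p = 0.0286 for each, adjusted p = 0.0857). Of 19506 regions, 5408 were covered more and 57 less (limma). Of the 5 named gained regions, 4 lay on chromosome 13, among them 51729965 to 51733328, which had no peak in tumours or control liver and rose to 98.8% ± 1.07 (difference 98.8 ± 7.34 points, limma adjusted p = 7.7e-06), and 45998576 to 46003142, which rose to 98.5% ± 1.72. The latter was bound by Myc in 6 of 6 tumours and covered by H3K27ac at 100% ± 0 before and after. On chromosome 17, 39979799 to 39985933 fell from 97.5% ± 1.85 to no peak (limma adjusted p = 1.29e-06), with 98.0% ± 2.29 in control liver. On chromosome 15, 96914966 to 96916825 rose from no peak in control liver to 90.5% ± 6.49 in tumours and had no peak after shutdown. With each library's mean coverage as a covariate 1 region was called, and mean coverage separated the groups completely, from 59.3% at the lowest after shutdown to 43.4% at the highest before. The count was 1334 with lists of equal length, 2524 with a stricter score limit, 3103 without tumour 3, 3363 without tumour 4, 3574 without switched-off tumour 2, 3478 without switched-off tumour 3 and 0 by Fisher tests (1761 at an unadjusted p below 0.05).

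H3K27ac domains were wider after shutdown. Median peak width was 8748 ± 182 bp in 3 switched-off tumours and 6386 ± 598 bp in 4 tumours with Myc on, and covered length was 199 ± 26.3 Mb against 124 ± 18.8 Mb (exact permutation p = 0.0286 for each, adjusted p = 0.0857). Peak numbers were 16014 ± 2126 and 14014 ± 1123 (exact permutation p = 0.2). Of 16039 regions, 1952 were covered more and 81 less (limma). On chromosome 19, 4063616 to 4064559 rose from no peak in control liver and tumours to 99.1% ± 0.441 (difference 99.1 ± 11.1 points, limma adjusted p = 0.000553), and H3K4me3 rose there to 100% ± 0. On chromosome 8, 93947591 to 93955116 rose to 97.8% ± 0.863. Among the regions covered less, chromosome 5, 122497470 to 122501272 fell from 91.3% ± 9.50 to no peak, and chromosome 1, 191509702 to 191513678 fell from 89.9% ± 6.55 to no peak while H3K4me3 was 74.0% ± 9.12 before and 89.4% ± 3.34 after. The count was 486 with mean coverage as a covariate, 939 with a stricter score limit, 1238 without tumour 4 and 0 by Fisher tests (668 at an unadjusted p below 0.05).

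Switched-off tumours still differed from control liver in chromatin. Their Myc lists held 223 ± 117 peaks against 3568 ± 3370 (SD, n = 3 and 4, exact permutation p = 0.0857, adjusted p = 0.171). Both groups covered little of the Myc regions, and in simulated data 3.5% of changes of 30 points were recovered, so few calls do not show that Myc was alike. For Myc, 2 regions were covered more and 24 less than in control liver, a count that fell to between 5 and 13 when any library was left out. With lists of equal length, which removes the difference in peak number in advance, 54 were called, 77.8% of them higher. RNAPII was covered more at 564 regions and less at 855. H3K4me3 was covered more at 8033 and less at 566, and H3K27ac more at 4912 and less at 587 (limma). The RNAPII direction turned without switched-off tumour 1 (62.5% of 1345 higher) and with mean coverage as a covariate (53.8% of 2225). It also turned with lists cut to equal length by peak width (50.9% of 950). Without switched-off tumour 2 the counts were 652 for RNAPII and 3515 for H3K27ac, and with mean coverage as a covariate 650 for H3K4me3 (68.9% higher, from 93.4%) and 2886 for H3K27ac (51.8% higher, from 89.3%), a far less clear direction. Equal list lengths gave 5057 and 2897, a stricter score limit 5254 and 2687, and wild-type controls alone 5361 for H3K4me3. Fisher exact tests on presence called 0 regions for Myc (312 at an unadjusted p below 0.05), RNAPII (1163), H3K4me3 (2385) and H3K27ac (1738).

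Some regions changed in tumours were called in the opposite direction after shutdown. For Myc, 16987 of the 18481 regions gained in tumours were lost (8126 for independent lists), and 11478 of 19101 (8860) with the tumour libraries divided between the contrasts, which otherwise share them. With so few Myc peaks after shutdown, bound regions had to fall. Of 658 regions that gained RNAPII in tumours, 139 lost it after shutdown, and of 1540 that lost it, 141 regained it (7.19 and 37.4 for independent lists). For H3K4me3, 45 of 1585 gained regions went down and 545 of 1302 lost regions went up (4.63 and 361), and for H3K27ac 75 of 1585 and 197 of 1056 (8.00 and 129). Another 116 regions that gained H3K4me3 and 57 that gained H3K27ac in tumours gained more after shutdown. With the libraries divided, gained and lost regions that went back numbered 34 and 50.7 for RNAPII (4.68 and 8.10), 18 and 257 for H3K4me3 (3.69 and 122) and 23 and 65.3 for H3K27ac (4.60 and 33.2). Simulated data without effects gave at most 0.05 such regions on average, but also called next to no region. Gained and lost regions that moved further numbered 1.33 and 1.67 for RNAPII, 131 and 0.667 for H3K4me3 and 53.2 and 0.167 for H3K27ac. A region covered in tumours has room to fall and one that lost its peaks has room to rise, and H3K4me3 and H3K27ac rose at most changed regions, so an excess over independent lists does not show a return to control liver. Across regions, the covariance of the RNAPII differences was -403, against -177 in simulated data without effects and -276 with the tumour libraries divided. The correlation was -0.438, against -0.464 in simulated data and -0.268 with the libraries divided, and correlations with and without real effects are not on the same scale, unlike covariances.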

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

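The tests with mean coverage as a covariate, of mean coverage with lists of equal length and with the wild-type control livers alone were chosen after the results they measure were seen, and the other tests in this part were set before.

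The Myc list of control liver 4 stood apart from the other 3 control lists. It covered 4.47 Mb where the nearest other control liver covered 0.460 Mb, and its median peak width was 444 bp where the nearest other was 132 bp. The gap to the nearest library was large relative to the range of the group in these 2 of 42 combinations of group and measure. Chance gives about 1 in 20, which over 42 is as many as were found, and both concern the same library. The narrowest peak of control liver 4 had 293 bp, within the range of tumours (239 to 328 bp), against 53 to 71 bp in control livers 1 to 3. The cause of this difference in width was not tested.

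Few Myc peaks were called after shutdown (223 ± 117, SD, n = 3, against 33786 ± 14095 in 6 tumours). Shorter lists of the same binding, as from weaker libraries, could give this, since a short list keeps the strongest peaks. Over 90% of the remaining peaks should then lie in regions bound in all 6 tumours, and under 50% would argue against it. The share was 64.0% ± 17.4 (SD, n = 3), between these bounds, so loss of binding and weaker libraries cannot be told apart from the lists. Peaks found in no tumour, such as those of 11 regions on chromosome 9 shared by the 3 switched-off lists, lower this share. Loss of Myc after 16 h of doxycycline, which the design gives, stays open as well.

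After shutdown 5408 H3K4me3 regions and 1952 H3K27ac regions were covered more, which lists that are longer throughout, for example from deeper sequencing, could give. With each library's mean coverage as a covariate 0.0183% of the called H3K4me3 regions and 23.9% of the H3K27ac regions were left. This does not decide the matter, because mean coverage of the switched-off tumours lay above that of all tumours with Myc on (lowest 59.3% against highest 43.4% for H3K4me3, and 40.3% against 38.0% for H3K27ac), so covariate and group cannot be told apart. With equal numbers of peaks per list 1334 H3K4me3 regions (93.3% higher) and 1532 H3K27ac regions (87.1% higher) were called, which argues against peak number as the whole cause. Yet mean coverage still separated the groups (lowest 61.5% against highest 57.8%, and 50.6% against 44.4%), so wider peaks from depth stay open, as does an effect of Myc loss.

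In tumours 60% of the called H3K27ac regions were higher than in control liver. With the wild-type control livers alone this share changed by -31.7 percentage points, so the direction may rest on control livers 1 and 2, which carried a transgene each and had shorter lists (72.9 and 90.5 Mb covered, against 147 and 153 Mb for numbers 3 and 4). Genotype and library quality cannot be parted here, as each transgene stands in 1 library. A change of the mark in tumours stays open as well. The named regions were covered in all 4 libraries of the higher group and in none of the lower, but they were chosen by that rule, so this is no support.

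For each count of changed regions, other splits of the same libraries into groups of the same sizes were fitted. For Myc, 3 of 100 splits drawn for tumours against control liver, and 4 of 84 for switched-off tumours against tumours, gave as many regions as the real split, which is counted among them. Both shares are under 0.05 without adjustment, but the highest other splits called 35605 and 37124 regions, against 18595 and 17229 for the real ones. They set the tumours with the longest lists against the rest, which points to a structure of list length among the tumours. For the remaining counts 1 of 35 splits, the real one, gave as many regions. For Myc in switched-off tumours against control liver the real count was 26 and the highest other 20, a narrow margin for a count that fell to between 5 and 13 without any 1 library, so nothing is rested on it. For the others the real count was the highest, but 1 of 35 is the smallest share possible and is not adjusted for the number of counts. Chance is therefore not excluded by this share alone. For tumours against control liver the real counts and highest others were 2198 and 23 (RNAPII), 2887 and 26 (H3K4me3) and 2641 and 1 (H3K27ac). For switched-off tumours against tumours they were 596 and 209, 5465 and 425, and 2033 and 241. For switched-off tumours against control liver they were 1419 and 112, 8599 and 3464, and 5499 and 2462.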

How the results depend on the processing

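Mean coverage as a covariate, chromosomes 1 to 19 alone, the term for Y chromosome peaks, wild-type controls alone and Myc regions built without the longest list were chosen after the data were seen. Outside the leave-one-out values, 89 alternatives kept direction and threshold or stayed within 1.5 times the reported count, 42 counts moved further, 13 turned, 4 results fell short of the threshold and 1 passed it. Depth is unknown, so list length limits every count. Windows around gene starts and ends, other gene starts and gene lists were not run for want of an annotation of the build, nor a score limit for RNAPII. Causes were not tested except where stated.

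Fisher exact tests called 7801 Myc regions for tumours against control liver and 0 for switched-off tumours against control liver. They called 0 for RNAPII, H3K4me3 and H3K27ac in all 3 contrasts, where too few regions reached the smallest possible p of 0.0286 for it to pass adjustment.

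With equal list lengths, which drop peaks from longer lists, Myc counts were 792 (tumours against control liver), 92 (shutdown, turned) and 54 (switched-off tumours against control liver, turned). Such a cut removes differences in peak number in advance, so these Myc directions do not bear on a general gain or loss. RNAPII lists were cut by peak width. RNAPII gave 950 for switched-off tumours against control liver (turned), H3K4me3 1334 for shutdown and 5057 against control liver, and H3K27ac 1758 for tumours (turned) and 2897 for switched-off tumours against control liver. The RNAPII difference at Myc-bound regions was 7.64 points (exact permutation p = 0.0857), and 34 Myc and 306 H3K4me3 regions changed in tumours and back.

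A stricter score limit gave 10172, 8825 and 2 Myc regions for tumours, shutdown and switched-off tumours against control liver. It gave 321, 2524 and 5254 for H3K4me3 and 310, 939 and 2687 for H3K27ac. The limit was the same for all libraries of an antibody, so lists with lower scores lost more peaks. Part of the direction under this limit is therefore fixed in advance. The compared groups alone gave 6 Myc regions and 848 RNAPII regions for switched-off tumours against control liver, and 154 RNAPII regions for shutdown.

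With mean coverage as a covariate, Myc counts were 9584, 9465 and 9. RNAPII counts were 1109 for shutdown and 2225 for switched-off tumours against control liver (turned). H3K4me3 counts were 3310 (turned), 1 (turned) and 650, and H3K27ac counts 3690 (turned), 486 and 2886.

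With wild-type controls alone, tumours gave 9863 Myc, 1308 RNAPII, 2523 H3K4me3 (turned) and 2974 H3K27ac regions (turned), and switched-off tumours 2 Myc and 5361 H3K4me3 regions. Without the longest list, 53 Myc regions were called for switched-off tumours against control liver.

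Covered length in place of peak number gave 26.8 Mb more RNAPII after shutdown (turned, exact permutation p = 0.371) and 74.6 Mb more H3K27ac (exact permutation p = 0.0286). RNAPII overlap with Myc regions present in every tumour turned to 0.976 points more than with control marks (exact permutation p = 0.743).

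With a replicate block, paired differences in peak number were 22781 and -21971 for Myc in tumours and after shutdown and 4420 for H3K4me3 after shutdown, with 4 or 3 pairs, too few for an exact sign-flip p under 0.05. The block gave 3443 H3K4me3 regions after shutdown and 1 Myc region for switched-off tumours against control liver (turned), and moved no other region count by over 1.5 times. A pairing by number was not shown: correlations of same-number deviations ran from -0.163 to 0.152, and in no contrast did every library correlate best with its own number. Presence of Y chromosome peaks matched by number between control livers and tumours, so a pairing of these stays open. It differed between tumour 1 and switched-off tumour 1.

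Leaving out each library in turn gave these lowest and highest values for tumours against control liver, shutdown and switched-off tumours against control liver. Myc regions ranged from 15440 to 22053, 13345 to 20555 and 5 to 13, the last moved by every library. RNAPII regions ranged from 1293 to 2092, 176 to 982 and 652 to 1345, H3K4me3 regions from 2098 to 2526, 3103 to 4520 and 6075 to 8445, and H3K27ac regions from 1807 to 2375, 1238 to 2699 and 3515 to 5478. Counts moved by over 1.5 times for RNAPII in tumours without control liver 1 or tumour 1, 2 or 3, for RNAPII after shutdown without tumour 1 or 2 or any switched-off tumour, and for RNAPII against control liver without switched-off tumour 2. They also moved for H3K4me3 after shutdown without tumour 3 or 4 or switched-off tumour 2 or 3, and for H3K27ac without tumour 4 (shutdown) or switched-off tumour 2 (against control liver). Directions turned for RNAPII without tumour 4 (658, shutdown) and without switched-off tumour 1 (1345, against control liver), for H3K4me3 without control liver 2 (2444) and for H3K27ac without control liver 1 (2375). Peak-number differences for tumours and shutdown ranged from 25823 to 33122 and -36467 to -29168 for Myc, -2805 to -767 and -3280 to -1524 for RNAPII, -130 to 811 and 3896 to 4583 for H3K4me3, and 1042 to 2523 and 1080 to 3164 for H3K27ac. The H3K4me3 difference in tumours turned to -130 without control liver 2, and the one after shutdown stood at an exact permutation p of 0.0667 or 0.1, the smallest possible with a library fewer.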

Other observations

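The tests of list length, of RNAPII at Myc-bound regions and of a return after shutdown were set before their results were seen, while the share of RNAPII regions of tumours that were Myc-bound and the observations without a stated test came after.

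Myc peaks called after shutdown overlapped H3K4me3 regions of control liver more often than those of tumours did. Of the peaks of the 3 switched-off tumours, 88.0% ± 2.88 (SD, n = 3) overlapped H3K4me3 regions of control liver, against 50.6% ± 11.8 in 6 tumours (exact permutation p = 0.0119, the smallest possible, adjusted p = 0.0714). H3K27ac regions without H3K4me3 held 0.743% ± 0.650 and 21.6% ± 2.83 (exact permutation p = 0.0119, adjusted p = 0.0714). In all 3 switched-off tumours 57 regions were present, of which 35 were also present in at least 2 tumours and 45 in at least 1 control liver. Of the 57, 11 lay on chromosome 9 between 2999852 and 3038237, none of them present in a tumour, and 4 on chromosome 2 between 98502244 and 98507574, places singled out after their values were seen. The chromosome 9 region from 2999852 to 3000508 had no H3K27ac peak in any library but was covered by H3K4me3 to 95.2% ± 5.57 in control liver (SD, n = 4). H3K4me3 covered 49.7% ± 57.4 of it in tumours and had no peak there in switched-off tumours. In control liver the chromosome 2 region from 98506197 to 98507574 was covered by H3K4me3 to 95.9% ± 4.78 and by H3K27ac to 75.0% ± 50.0. In tumours these were 73.4% ± 49.0 and 25.0% ± 50.0. In switched-off tumours H3K4me3 covered 99.6% ± 0.670 of it and H3K27ac had no peak. Mitochondrial peaks made up 1.67% to 6.95% of the switched-off lists and none of the tumour lists. Peaks seen after shutdown and in no tumour cannot be taken as Myc binding from the lists alone, though some count in the 88.0% above. Regions of at least 2 tumours held from 62.2% to 82.0% of the peaks of each switched-off list. The switched-off lists were the shortest of all, and within tumours the peaks with the highest scores also lay more often at H3K4me3.

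RNAPII domains were long in some groups. Domains of at least 50 kb numbered 86.3 ± 23.2 in control liver, 27.3 ± 44.0 in tumours and 211 ± 148 in switched-off tumours (SD, n = 4, 4 and 3). Neither the drop in tumours (exact permutation p = 0.114, adjusted p = 0.343) nor the rise after shutdown (exact permutation p = 0.0571, adjusted p = 0.229) passed. For H3K27ac such domains numbered 66.5 ± 39.4 in tumours and 299 ± 79.1 after shutdown (exact permutation p = 0.0286, adjusted p = 0.229).

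Peaks on the Y chromosome were present for RNAPII, H3K4me3 and H3K27ac in control livers 1 and 3, tumours 1 and 3 and switched-off tumour 3, and for none of these antibodies in the other 6 numbered livers or tumours. Libraries with the same group and number thus matched across these 3 antibodies.

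One hypothesis was that the share of Myc peaks at H3K4me3 falls with list length, so that tumours with longer lists add weaker sites outside promoters. Over 6 tumours the share fell with peak number (Pearson r = -0.989, exact permutation p = 0.00139, adjusted p = 0.00208, Spearman rho = -1, exact permutation p = 0.00278). Without the 2 tumours farthest from the median list length r was -0.973. The share has peak number as its denominator, so part of this fall is built in and the p-values are weak support. Peaks at H3K4me3 numbered 12372 in tumour 1 and 18485 in tumour 6, while the lists held 19269 and 55763 peaks. Tumours 5 and 6, with the longest lists, were also the only libraries with peaks on unplaced (random) sequence, 24 and 25. What sets them apart was not tested. Differences between tumours in where Myc binds may therefore reflect how many peaks were called. The labels do not say which tumours expressed the mutant form, so that explanation was not tested.

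Another hypothesis was that RNAPII gains in tumours occur more often at Myc-bound regions. The odds ratio matched for length and control coverage was 2.03, while the unmatched one was 1.15 (Fisher exact p = 0.196). Only a region with RNAPII in tumours can be called higher, and 86.9% of these were Myc-bound, against 82.1% of the gained regions. For binding in all 6 tumours the order turned, with 63.3% and 66.9% (odds ratio 1.83, matched 3.04). The gained regions were merged over all groups and the regions with RNAPII in tumours over tumour libraries alone, so these shares are not of like regions. A link between Myc binding and RNAPII gain and the frequent binding of Myc where RNAPII lies cannot be told apart here.

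A last hypothesis was that RNAPII changes in tumours return towards control liver after shutdown. With the tumour libraries divided between the contrasts, the covariance of the differences was -276, which is consistent with a partial return, but any feature shared by the libraries of tumours with Myc on, or the room of lost regions to rise, would give the same. With all tumour libraries in both contrasts the covariance was -403 against -177 in simulated data without effects, while the correlation was -0.438 against -0.464. Of the gained regions 139 of 658 and of the lost regions 141 of 1540 were called in the opposite direction after shutdown, so most were not called again at 16 h. A region not called may still have changed. With the tumour libraries divided, mean coverage was lower after shutdown at 73.3% of gained regions and higher at 54.3% of lost ones. The limits given for the covariance hold for these shares too.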
